A study of Arabidopsis thaliana with 12 samples.

How the data were processed

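RNA abundance was measured in whole plants of the Arabidopsis thaliana accession Col-0 on 12 single-colour Affymetrix arrays. Per the labels, 3 total RNA samples were used: an untreated control, plants exposed to 0.1 µM indole-3-acetic acid (IAA, a natural auxin) for 1 h, and plants exposed to it for 3 h. Each RNA was hybridized 2 times to the ATH1 array and 2 times to the smaller, earlier AG array, which gave 6 arrays per platform. The labels number the plants of each condition as the first of several biological samples, and the other biological samples were not analysed here. With 1 biological sample per condition the spread between arrays was technical, so no test of the treatment was possible. The labels mark both ATH1 hybridizations of the control RNA as coming from a first labelling, and the treated RNAs carry no such remark. In the titles the mark (a) follows the control hybridizations on both platforms and none of the treated ones.

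The deposited values are probe set intensities on a linear scale, 1 per probe set and array. Per the labels, the authors scaled each array, with scaling factors of 2.8 to 6.5 on ATH1 and 3.3 to 5.0 on AG. In the files the 2% trimmed mean of each array lay between 499.5 and 499.6 on ATH1 and between 500.7 and 500.8 on AG. The software that summarised the probes and any detection calls are not given in the sources used here. Scaling to 1 level sets the bulk of the arrays equal, so a difference shared by most transcripts cannot be seen.

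Signals were analysed as log2(signal + 25.0), the added amount being 5% of the trimmed mean of the platform. A probe set was used when its mean signal over the 6 arrays was at least 25% of that trimmed mean, which was 124.9 on ATH1 and 125.2 on AG. It was called higher or lower when the means of 2 RNA samples differed by at least 1 on the log2 scale (2-fold) and both hybridizations of one RNA lay above both of the other. The count that hybridization error alone would give was computed by applying the size threshold to differences built from the half-differences between hybridizations of the same RNA. Contrasts were 1 h minus control, 3 h minus control and 3 h minus 1 h, each platform alone. The limma package was fitted to the 6 hybridizations of a platform with 1 shared estimate of the hybridization spread, and a Benjamini-Hochberg adjusted p under 0.05 was counted. That model compares the RNA samples, not the treatments, because the hybridizations of 1 RNA are not biological replicates. The exact binomial method gave 95% intervals for shares of calls.

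The contrasts, the rule for calls, the 19 gene lists, the rule for named genes and most of the alternatives were chosen before the data were examined. Control probe sets, 64 on ATH1 and 50 on AG, were left out of the minimum, the calls and the models, which was decided on seeing the files. The trimmed mean was at first taken without the control probe sets. After the first counts of calls had been seen it was taken over every probe set, which is how the files are scaled, and the earlier version is among the alternatives.

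Probe sets were linked to genes through the probe tables of the platforms and a RefSeq gene table for assembly TAIR10.1, used for names and not for positions. On ATH1, 13513 probe sets named 1 gene, 503 named several and 8730 named no gene in the tables used. On AG these numbers were 3794, 70 and 4383. Of the ATH1 probe sets naming 1 gene, 13436 were matched by gene identifier, 48 by locus tag and 29 not at all; on AG the numbers were 3784, 8 and 2. Where several probe sets named a gene, the one with the highest mean signal represented it. List members with no named probe set were not analysed here.

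The gene lists covered Aux/IAA repressors, GH3 enzymes, SAUR genes, LBD factors of lateral roots, auxin receptors and ARF factors, auxin transport, auxin and tryptophan metabolism, other early auxin genes, ethylene synthesis, expansins with XTH wall enzymes, type-A response regulators of cytokinin, gibberellin and brassinosteroid metabolism, the cell cycle, touch and handling, heat shock, the circadian clock, photosynthesis, root markers and reference genes. A list with at least 3 members above the minimum signal was compared with 10000 random lists of the same size matched on mean signal, as a description of these samples; the Aux/IAA list was not ranked, because members entered it through their treated signal. The rule for named genes had 4 parts. It took called members of the lists and the reference genes; for 1 h and for 3 h against the control, among genes called in the same direction on both platforms, the 10 highest and the 10 lowest by the mean of the platforms' differences; among genes named by ATH1 alone, the 5 highest and the 5 lowest by the smallest of the 4 differences between single hybridizations; and up to 5 genes per contrast called in opposite directions, of which there were 0.

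The steps were tested on simulated data made for 3 h minus control with 13883 probe sets on ATH1 and 4311 on AG. On ATH1 the rule for calls recovered 36% of simulated differences of 1, 96% of those of 1.5, 90% of those of 2 and 96% of those of 3 on the log2 scale, with 1 false call. On AG it recovered 24%, 92%, 92% and 98% of the same sizes, with 0 false calls. For limma the recovered percentages were 68, 97.9, 100 and 100 on ATH1 with 4 false calls, and 91.7, 100, 100 and 100 on AG with 6. The limma percentages are over the simulated differences above the minimum signal, 50, 48, 45 and 48 on ATH1 and 48, 48, 46 and 49 on AG. Those of the rule for calls are over all 50 of each size. At 1.5, 2 and 3 on ATH1 the rule recovered 48, 45 and 48, and limma 47, 45 and 48. For the list percentile, simulated for 3 h minus control on 14006 ATH1 probe sets, 5 of 100 lists of 5 unshifted members and 91 of 100 lists shifted by 0.5 lay outside the central 95%.

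The alternatives chosen at the outset were quantile normalization, scaling on the genes that both platforms measure, no added amount with signals below 1 set to 1, an added amount of 20%, no minimum signal, a minimum of 50%, calls by size alone, an intensity trend and the hybridization number as a block in limma, and leaving out each hybridization in turn. Added after the data had been seen were the trimmed mean without control probe sets, calls without chloroplast-encoded probe sets, and a block on AG with the hybridization numbers of the 3 h RNA crossed. A scan of gene families by the letters of their symbols, with at least 5 members, was also added then; it left out symbols that start with GH. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.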

Results

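The data are intensities from 3 whole-plant RNA samples, each hybridized 2 times to the ATH1 array and 2 times to the AG array: an untreated control, 1 h of IAA and 3 h of IAA. ATH1 held 22810 probe sets, of which 14006 were above the minimum signal, and AG held 8297, of which 4325 were. On single arrays 36.7% to 39.4% of the ATH1 probe sets and 47.1% to 49.0% of the AG probe sets lay below that minimum. Differences are log2 treated minus control with the SE between hybridizations (n = 2 against 2), and each condition had 1 biological sample. The number of arrays limits the precision of every value. A separate labelling of the control RNA, which the labels leave possible, would enter every contrast with the control.

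The comparison of the 1 h RNA with the control asked which transcripts differ early after auxin. GH3.3 (AT2G23170) and GH3.5 (AT4G27260), which encode enzymes that conjugate IAA to amino acids, were higher in the 1 h RNA on both platforms. The GH3.3 signal on ATH1 was 251 ± 28.4 in the control and 9869.8 ± 426 after 1 h (SD, n = 2 hybridizations), a difference of 5.17 ± 0.11; on AG it was 5.60 ± 0.09. GH3.5 was higher by 2.90 ± 0.05 on ATH1 and 2.82 ± 0.03 on AG. HAT2 (AT5G47370), an HD-Zip transcription factor on the list of other early auxin genes, was higher by 3.23 ± 0.09 on ATH1 and 3.49 ± 0.14 on AG. LBD16 (AT2G42430) and LBD29 (AT3G58190), transcription factors of lateral root formation, were both above the minimum on ATH1; LBD29 differed by 3.82 ± 0.03 there, and LBD16 by 1.72 ± 0.13 on ATH1 and 1.85 ± 0.05 on AG.

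Of the 29 Aux/IAA repressors of auxin signalling, 3 were above the minimum on ATH1, with a median difference of 2.30. IAA29 and IAA30 passed the minimum through their signal in the treated RNAs, so the list was not ranked among random lists; over the 7 members with a named probe set the median was 0.56, and with arrays scaled on the genes both platforms measure it was 1.18. IAA29 (AT4G32280) was higher by 2.34 ± 0.14 and IAA30 (AT3G62100) by 2.30 ± 0.28, while IAA18 (AT1G51950) differed by 0.10. IAA30 lay below the minimum under that scaling. In the control RNA the signals of LBD29, IAA29 and IAA30 on ATH1 and of GH3.3, LBD16 and SAUR10 on AG were under the minimum, so the size of their differences depends on the added amount. On AG the 2 Aux/IAA genes above the minimum had a median of 0.22 and neither was called. The 3 GH3 genes above the minimum on ATH1 had a median of 2.90 at the 100th percentile of random lists, or 2.12 with no minimum signal, with GH3.17 (AT1G28130) at 0.22. SAUR10 (AT2G18010), the single SAUR gene above the minimum and so on AG alone, was higher by 2.89 ± 0.78. XTH18 (AT4G30280), which encodes a xyloglucan-modifying wall enzyme, was higher by 1.38 ± 0.11 on ATH1, and the 4 measured genes of the expansin and XTH list had a median of 0.59 at percentile 99.97. The medians of the wider families, taken after the data had been seen, lay inside the 95% range of random lists: 8 EXPA genes had a median of -0.04 at percentile 34.83 and 7 XTH genes -0.12 at percentile 16.73.

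**Figure D1:**
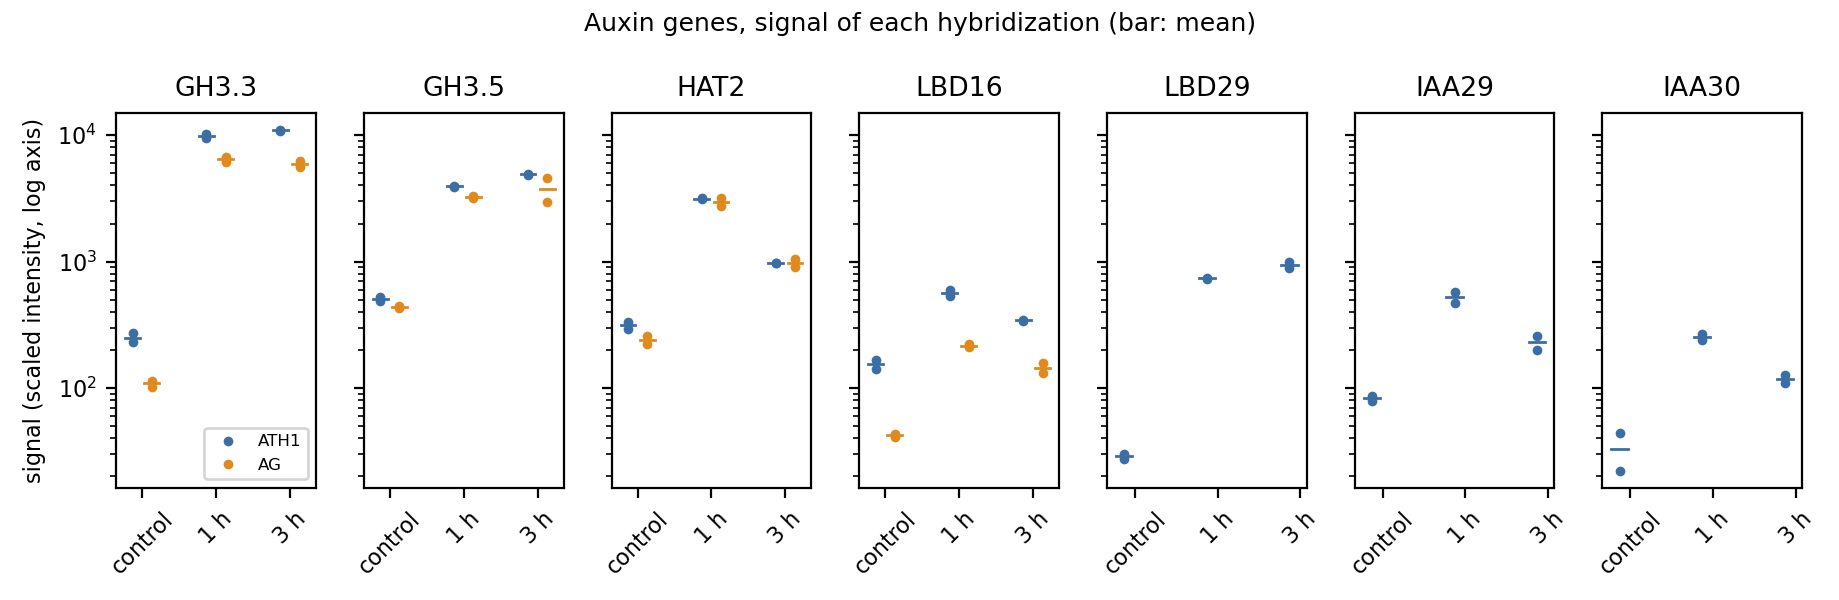
Signal (scaled intensity, log axis) of 7 auxin genes in the control, 1 h and 3 h RNAs, 1 point per hybridization, coloured by platform, with bars at the means. GH3.3 stands at 9869.8 after 1 h on ATH1 against 251 in the control, and HAT2 is lower at 3 h than at 1 h on both platforms.

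Beyond the lists, LTI30 (AT3G50970), a dehydrin, was higher in the 1 h RNA by 1.33 ± 0.07 on ATH1 and 1.30 ± 0.10 on AG. AT2G41380, of a methyltransferase family, was higher by 1.13 ± 0.03 and 1.17 ± 0.08, and AT3G15450 by 1.06 ± 0.02 and 1.17 ± 0.14. AT1G10140 differed by 1.18 on ATH1 and 1.33 on AG, and AT4G13180 by 1.13 and 1.11. Among genes named by ATH1 alone, GSTU25 (AT1G17180), a tau-class glutathione S-transferase, was higher by 1.29 ± 0.07, AT3G51410 by 1.33 ± 0.07 and AT5G41400 by 1.61 ± 0.32. The lowest genes of that group were encoded by the chloroplast genome, among them ndhE at -2.42 ± 0.25, ndhJ at -2.26 ± 0.19 and rpl20 at -2.16 ± 0.16. LHCB4.3 (AT2G40100), a light-harvesting protein, was lower by the rule on AG at -1.31 ± 0.06 and stood at -0.92 ± 0.08 on ATH1; 0 genes were called lower on both platforms at 1 h.

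In total 99 probe sets were called higher and 51 lower at 1 h on ATH1, against 13 to 15 calls from hybridization error alone, and 39 higher and 6 lower on AG, against 1 to 2. Without hybridization 2 of the 1 h RNA, the ATH1 calls were 276, of which 145 were higher. Differences over 3 on the log2 scale numbered 6 on ATH1 and 5 on AG.

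The comparison of the 3 h RNA with the control asked what differs after longer exposure. The labels give no time for the control, and the same control RNA serves both times. Other changes over those hours are therefore not separated from exposure to IAA. GH3.3 stood at 5.31 ± 0.11 on ATH1 and 5.48 ± 0.11 on AG, GH3.5 at 3.22 ± 0.05 and 3.00 ± 0.30, and LBD29 at 4.16 ± 0.07 on ATH1. HAT2 was higher than in the control by 1.56 ± 0.09 on ATH1 and 1.92 ± 0.14 on AG. LBD16 was higher by 1.04 ± 0.11 and 1.33 ± 0.11, and without hybridization 1 of the control its ATH1 value was 0.94, under the 2-fold threshold. IAA29 was higher by 1.23 ± 0.18, IAA30 by 1.32 ± 0.29 and XTH18 by 1.17 ± 0.06, while SAUR10 on AG differed by 0.90 ± 0.89, less than 2 of its SE. The Aux/IAA median on ATH1 was 1.23, or 0.28 over the 7 members with a named probe set and 0.87 with scaling on shared genes. The GH3 median was 3.22 at the 100th percentile, or 1.90 with no minimum signal. The 4 measured genes of the expansin and XTH list had a median of 0.69 at percentile 99.92, while the 8 EXPA and 7 XTH genes of the wider families had 0.04 (percentile 56.5) and 0.07 (percentile 67.04).

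Single genes of several enzyme classes were higher in the 3 h RNA. The medians of the wider GSTU and UGT families were -0.37 and -0.02, with 2 of 8 and 3 of 27 genes called higher. In GSTU 2 genes were called lower. GSTU25 was higher by 3.39 ± 0.03, and UGT73B4 (AT2G15490), a glucosyltransferase, by 2.62 ± 0.15. The UGT73B4 control signal of 36.5 was under the minimum, so the size depends on the added amount; with scaling on shared genes the difference was 2.49, and the mean signal fell short of the minimum, which ended the call. AT2G41380 stood at 3.07 ± 0.05 on ATH1 and 2.90 ± 0.09 on AG, AT4G01870 at 2.52 ± 0.10 and 2.29 ± 0.08, and AT2G18190 at 1.93 ± 0.15 and 1.71 ± 0.24. AT2G19970 was higher by 1.82 and 1.49, AT2G32020 by 1.71 and 1.61, AT4G17350 by 1.64 and 1.5, and AT4G13180 by 1.41 and 1.46. With a minimum signal of 50% the AG calls of AT2G18190, AT2G32020 and AT4G17350 were lost. AT1G62770, a pectin methylesterase inhibitor, was higher by 3.06 ± 0.09 on ATH1, and AT1G64405, whose control signal was under the minimum too, by 2.80 ± 0.10. LTI30 was higher by 1.55 ± 0.10 and 1.35 ± 0.14.

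Lower in the 3 h RNA were AT4G36700, which encodes a cupin, at -2.74 ± 0.08 on ATH1 and -2.72 ± 0.20 on AG, and the peroxidase gene AT3G01190 at -2.01 ± 0.04 and -1.95 ± 0.21. AT4G11210, a dirigent protein, stood at -1.75 ± 0.12 and -1.49 ± 0.08, and AT2G42690 at -1.47 ± 0.06 and -1.60 ± 0.15. AT2G39980 differed by -1.18 and -1.34, AT2G36690 by -1.12 and -1.37, AT1G62510 by -1.26 and -1.23, GSTU18 (AT1G10360) by -1.16 and -1.27, LHCB4.3 by -1.12 and -1.29, and ECS1 (AT1G31580) by -1.19 and -1.11. Among genes named by ATH1 alone, AT1G47400, a small peptide of the iron-deficiency response, was lower at -3.31 ± 0.05, and AT5G03350, a lectin, at -2.72 ± 0.13. ARR16 (AT2G40670), a type-A response regulator of cytokinin signalling, was lower on ATH1 at -1.14 ± 0.19, and without hybridization 2 of the 3 h RNA at -0.95, inside the 2-fold threshold.

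At 3 h, 214 probe sets were called higher and 173 lower on ATH1, against 0 to 1 from hybridization error, and 82 higher and 71 lower on AG, against 1 to 2. Differences over 3 numbered 10 on ATH1 and 6 on AG. On ATH1 53 probe sets were called higher at both times and 30 lower at both, 20 of the 30 being chloroplast-encoded; on AG the numbers were 22 and 3, with 0 opposite calls. Both contrasts share the control arrays. In 100 simulations of unchanged RNAs with normally distributed hybridization error and shared controls, the highest overlap was 0. Normal error of this size hardly ever reaches 2-fold in both contrasts, so that result was likely from the start. It does not cover rarer, larger errors of single hybridizations. A difference of the control plants themselves, or a separate labelling of the control RNA, would enter both contrasts and is not covered by that simulation.

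Further lists gave few called genes. Of the reference genes, UBC21 (AT5G25760) stood at -0.21 ± 0.05 and 0.08 ± 0.04 at 1 h and 3 h on ATH1, and TIP41L (AT4G34270) at -0.19 ± 0.03 and 0.04 ± 0.04. Root markers (EXPA7, EXPA18 and the beta-glucosidase gene PYK10) had ATH1 medians of 0.19 and -0.35, at percentiles 75.56 and 3.1. From the list of touch and handling, ZAT10 stood at 0.48 on ATH1 and 0.60 on AG at 1 h, and WRKY53 at 0.03 and 0.09; at 3 h they stood at 0.34 and 0.46, and at -0.22 and -0.24. The clock gene GI differed by 0.13 and -0.01 at 1 h and by 0.27 and -0.03 at 3 h. LHCB4.1, from the photosynthesis list, differed by -0.05 and 0.03 at 1 h and by -0.39 and -0.21 at 3 h. WAG2, from auxin transport, stood at 0.12 and 0.17 at 1 h and 3 h on ATH1, and YUC2, from auxin and tryptophan metabolism, at 0.20 and -0.25; none of these was called. The heat shock gene HSP17.6C lay below the minimum on both platforms. For auxin receptors and ARF factors, ethylene synthesis, gibberellin and brassinosteroid metabolism and the cell cycle, 0 members had a named probe set.

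The direct contrast of 3 h with 1 h asked which transcripts differ between the times. HAT2 was lower at 3 h than at 1 h by the rule, at -1.67 ± 0.01 on ATH1 and -1.57 ± 0.15 on AG, and SAUR10 was at -1.99 ± 0.50 on AG. AT2G41380 was higher at 3 h by 1.95 ± 0.04 and 1.73 ± 0.08, and AT4G36700 was lower at -2.22 ± 0.08 and -2.23 ± 0.20. EXPA8 (AT2G40610), an expansin, was called on ATH1 at 1.33 ± 0.73, and at 0.61 without hybridization 1 of the 1 h RNA it was not. The Aux/IAA median on ATH1 was -0.98 over the 3 members above the minimum, of which IAA29 and IAA30 passed it through their treated signal. IAA30 lay below the minimum with scaling on shared genes. In this contrast 137 probe sets were called higher and 108 lower on ATH1, against 9 to 10 from hybridization error, and 46 and 37 on AG, against 0 to 2.

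As a group, chloroplast-encoded transcripts were lower in both treated RNAs than in the control on ATH1. The group includes transcripts of the NADH dehydrogenase-like complex and the ribosome. Their 66 probe sets had a median of -0.63 at 1 h (quartiles -1.28 and -0.35) and -0.79 at 3 h (quartiles -1.32 and -0.40). Random lists of the same size and signal had 95% ranges of -0.03 to 0.10 and -0.03 to 0.12. Of the 66, 61 at 1 h and 64 at 3 h were below 0, and 23 and 24 were called lower; the median of 3 h minus 1 h was -0.09, with members from -0.67 to 0.97. At 3 h psaC stood at -2.14 and rps15 and ndhE at -2.15, ycf3 at -2.11, ndhJ at -2.04, rpl20 at -1.74 and atpF at -1.15. Over the alternatives run the median stayed between -0.69 and -0.57 at 1 h and between -0.82 and -0.72 at 3 h. AG named 0 chloroplast-encoded genes in the tables used, so the group was measured on 1 platform. Control spikes on ATH1 differed from the control RNA too, dap by -0.57 and -0.58 and trp by -0.61 and -0.55 at 1 h and 3 h. The thr probe sets, dim at 53.0 to 288.0 in the control, were lower too, by -0.82 to -0.18 at 1 h and -1.14 to -0.36 at 3 h. In the other direction went lys (0.21 and 0.16) and phe (0.37 and 0.23). The cre control was also higher (0.36 and 0.14) and is not read here as evidence on labelling. A separate labelling of the control is therefore not excluded for this group.

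**Figure D2:**
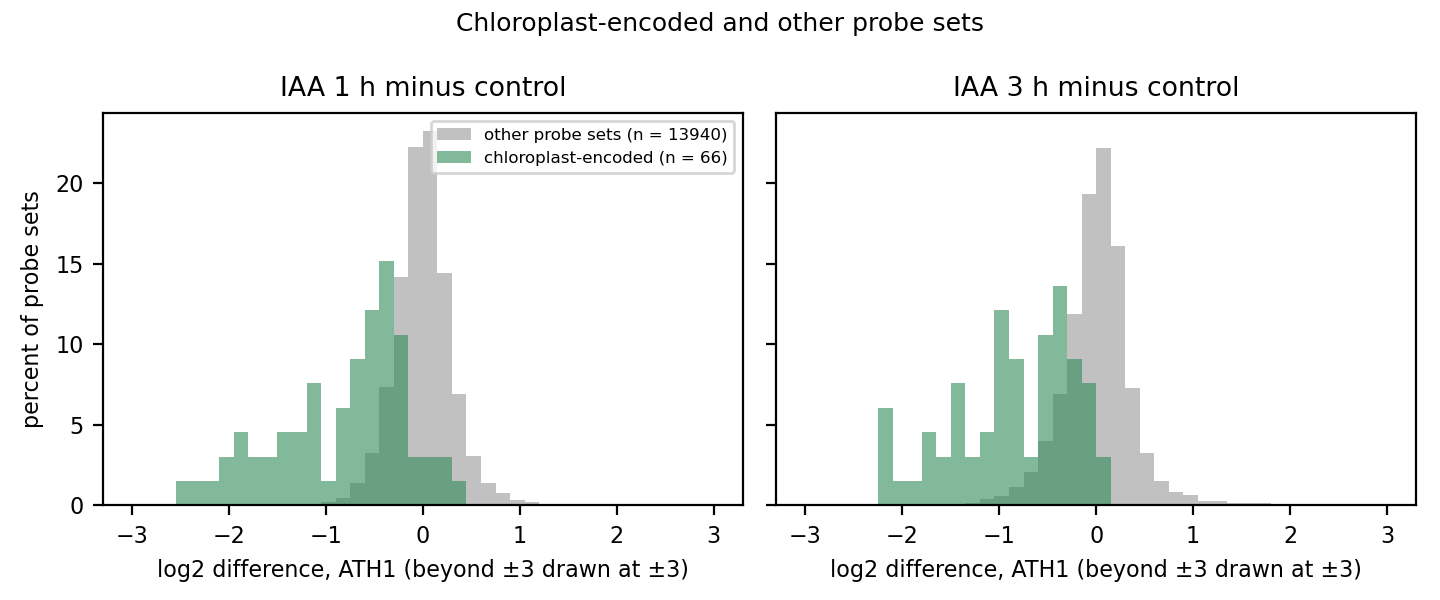
Distribution of log2 differences from the control on ATH1 for 66 chloroplast-encoded and the other probe sets at 1 h and 3 h, as percent of each group, with values beyond 3 drawn at the edge. The chloroplast-encoded group is shifted below 0 at both times, with medians of -0.63 and -0.79.

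The series set the platforms side by side with the same RNA. Of 3047 genes named on both, 1485 were above the minimum on both, 554 on ATH1 alone, 32 on AG alone and 976 on neither. GH3.3, GH3.5, HAT2 and LBD16 were called on both platforms at both times. Across the 1485 genes, which are not independent replicates, Pearson's r of the differences was 0.754 at 1 h (95% interval 0.731 to 0.775), 0.861 at 3 h (0.847 to 0.873) and 0.727 for 3 h minus 1 h (0.702 to 0.75), and Spearman's rho was 0.526, 0.745 and 0.604. The slope of AG on ATH1 was 0.99, 1.07 and 1.02. The platforms' differences had an SD of 0.236, 0.229 and 0.245 around each other, where hybridization error alone gave 0.199, 0.187 and 0.223. Among the brightest of 3 equal groups of genes r was 0.894 at 1 h, among the middle group 0.623 and among the dimmest 0.622.

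At 1 h 14 of the shared genes were called on ATH1 and 10 on AG, 9 of them on both in the same direction; at 3 h the numbers were 36, 43 and 29, and for 3 h minus 1 h they were 19, 21 and 15. Of genes higher at 3 h, 17 were called on both where independent calls would share 0.337, and of genes lower 12 where they would share 0.194. No gene was called in opposite directions. The platforms differed by under 1 log2 unit for 1483, 1484 and 1481 of the 1485 genes in the 3 contrasts. The exceptions, chosen after their values were seen, were BRK1 (-0.99 ± 0.02 on ATH1 and 0.04 ± 0.09 on AG) and EXPA8 (-0.84 ± 0.72 and 0.16 ± 0.10) at 1 h and AT4G26010 (-0.93 ± 0.01 and -2.52 ± 0.54) at 3 h. For 3 h minus 1 h they were EXPA8, AT4G26010, ATG8E (0.87 ± 0.51 and -0.19 ± 0.08) and AT4G29030 (0.36 ± 1.13 and -0.68 ± 0.19). For signal levels, r of log2 signal over the 1485 genes was 0.820 in the control, 0.812 at 1 h and 0.803 at 3 h, and 516, 541 and 555 genes differed at least 2-fold in level.

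**Figure D3:**
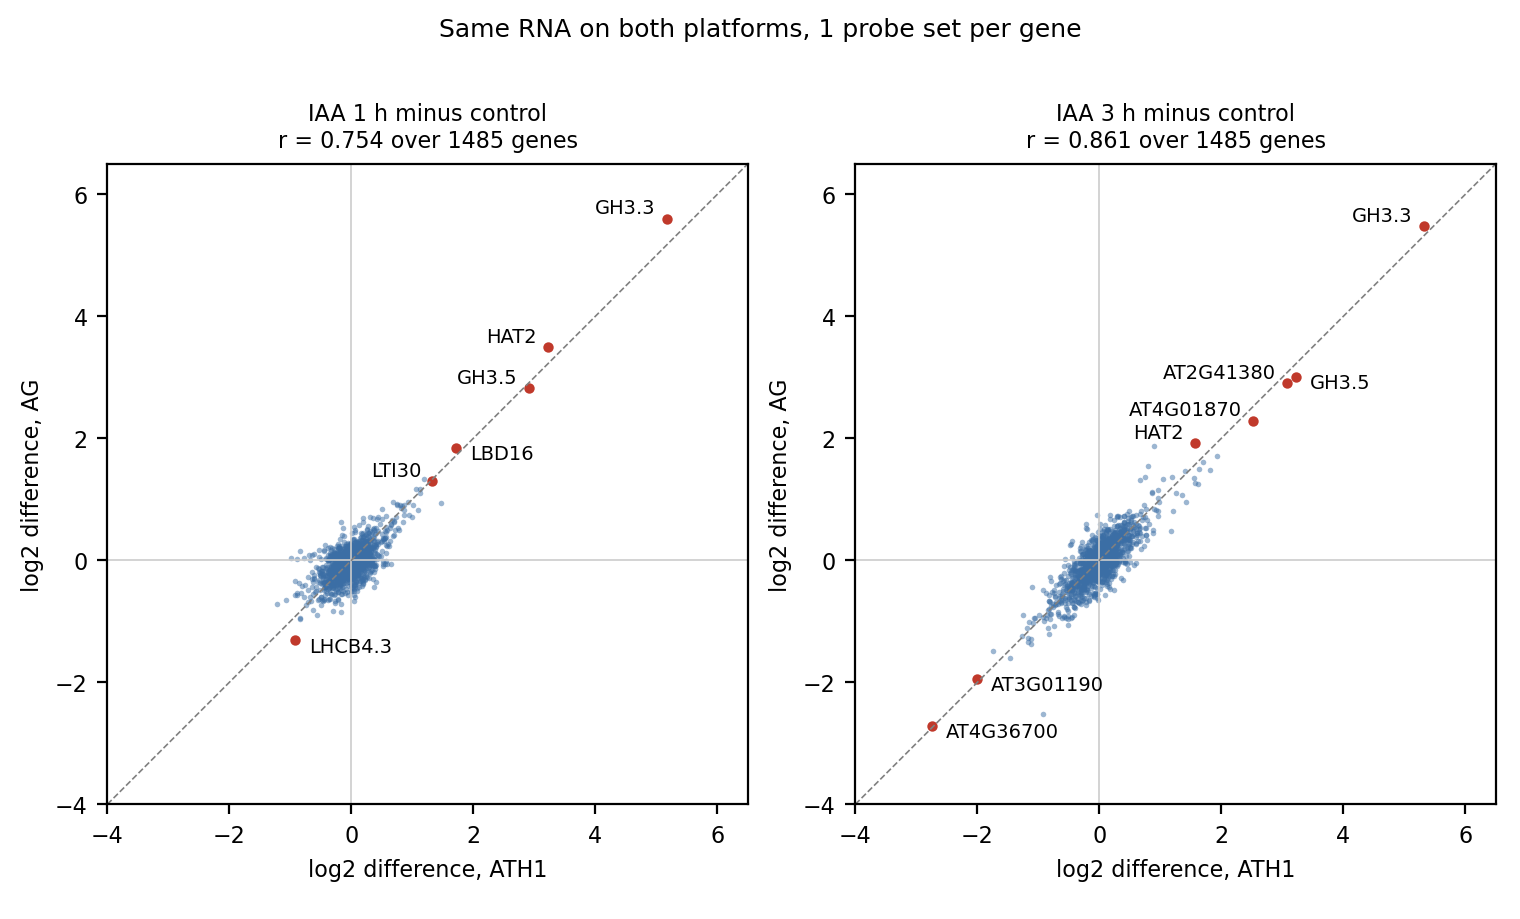
Log2 difference on AG against that on ATH1 for genes above the minimum on both platforms, 1 point per gene, with 1 h and 3 h minus control in separate panels and labels on named genes. Labelled genes lie near the diagonal, with GH3.3 at 5.17 and 5.60 at 1 h, while AT4G26010, unlabelled, lies off it at 3 h at -0.93 and -2.52.

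The spread between hybridizations of the same RNA was widest for the 1 h RNA on ATH1. The SD of the log2 difference between the hybridizations was 0.173 for the control, 0.291 for 1 h and 0.193 for 3 h on ATH1, and 0.172, 0.208 and 0.245 on AG. For the 1 h RNA on ATH1, whose hybridization 1 has the highest scaling factor of 6.5, 105 probe sets were at least 2-fold apart, against 8 and 15 for the other RNAs. Its SD was 0.405 in the dimmest of 3 equal groups of probe sets and 0.157 in the brightest.

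By limma over hybridizations, which compares the RNA samples, GH3.3 and HAT2 were past the threshold on both platforms. So were 127 of the 128 called values of named genes. The exception was EXPA8 for 3 h minus 1 h on ATH1, with a limma adjusted p of 0.10. Those values had been called from the same arrays by size and by separation of the hybridizations, so their passing was largely set in advance and is no separate support. On ATH1 574 probe sets were higher and 599 lower at 1 h, 1232 and 1469 at 3 h, and 842 and 886 for 3 h minus 1 h. On AG the numbers were 199 and 197, 565 and 686, and 310 and 388. With no minimum signal the ATH1 totals were 147, 1054 and 461 and the AG totals 91, 824 and 280, and with an intensity trend the ATH1 totals were 2469 at 1 h and 2874 for 3 h minus 1 h. Of the 25 list members above the minimum on ATH1, 9, 14 and 9 passed in the 3 contrasts when adjusted over all probe sets, and 13, 17 and 15 when adjusted over the list alone. For the 13 on AG the counts were 7, 7 and 3 both when adjusted over all probe sets and when adjusted over the list alone. These totals rest on few arrays: without hybridization 1 or 2 of the control, the ATH1 total of 1173 at 1 h was 64 or 59, and the 2701 at 3 h was 621 or 680. Without those of the 1 h RNA the first was 750 or 1949, and without either of the 3 h RNA 358; without those of the 3 h RNA the second was 844 or 871. The ATH1 total of 1728 for 3 h minus 1 h was 692 without either control hybridization and 207 or 258 without those of the 3 h RNA. On AG the total of 396 at 1 h was 85 or 67 without those of the control and 126 or 142 without those of the 1 h RNA, and the 1251 at 3 h was 543 or 498 without those of the control. The AG total of 698 for 3 h minus 1 h was 439 without either of the control, 229 or 248 without those of the 1 h RNA and 450 without hybridization 1 of the 3 h RNA.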

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

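The direct contrast of 3 h with 1 h was planned, and the comparison of the control probe set was a test chosen after its value was seen. Several named genes differed between the 3 h and 1 h RNAs by the contrast of those RNAs itself, which asked whether the RNAs of the 2 times differed. HAT2, an HD-Zip transcription factor, was lower at 3 h, at -1.67 ± 0.01 on ATH1 and -1.57 ± 0.15 on AG (SE between hybridizations, n = 2 against 2), and so was AT3G15450, at -1.15 ± 0.02 and -1.25 ± 0.14. The Aux/IAA repressor IAA29 was lower at -1.11 ± 0.21 on ATH1; without hybridization 2 of the 1 h RNA it stood at -0.98, and without hybridization 1 of the 3 h RNA at -0.94, neither of them called. Lower at 3 h too were AT4G36700 (-2.22 ± 0.08 and -2.23 ± 0.20), the peroxidase gene AT3G01190 (-1.37 ± 0.03 and -1.51 ± 0.25), AT4G11210 (-1.98 ± 0.09 and -1.57 ± 0.09) and AT2G36690 (-1.34 ± 0.04 and -1.67 ± 0.15). On ATH1 alone, AT1G47400 was lower at -2.36 ± 0.05 and AT5G03350 at -2.81 ± 0.23.

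Higher at 3 h than at 1 h on both platforms were AT2G41380 (1.95 ± 0.04 and 1.73 ± 0.08), AT4G01870 (1.66 ± 0.13 and 1.47 ± 0.06), AT2G18190 (1.57 ± 0.33 and 1.91 ± 0.23) and AT2G19970 (1.27 ± 0.10 and 1.12 ± 0.16). Without hybridization 1 of the 3 h RNA, the AG value of AT2G19970 was 0.96 and not called. On ATH1 alone the tau-class glutathione S-transferase GSTU25 was higher by 2.09 ± 0.07, the pectin methylesterase inhibitor gene AT1G62770 by 2.42 ± 0.07, AT1G64405 by 1.62 ± 0.06 and the glucosyltransferase gene UGT73B4 by 1.99 ± 0.26. The genes listed here were called in this contrast, so by the rule for calls both hybridizations of one RNA lay beyond both of the other. The limma adjusted p, taken from the same arrays, ran from 0.00022 to 0.011. That p compares 2 RNA samples, each from 1 biological sample, so a difference between plants grown or handled apart is not separated from the time of exposure.

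The probe set for 25S ribosomal RNA is a control outside the gene comparisons, and it was higher in the 3 h RNA than in the control RNA. On AG the difference was 1.22 ± 0.20 and on ATH1 0.86 ± 0.13, while at 1 h it was -0.05 and 0.20. Other control probe sets were higher at 3 h too, with the same sign under each scaling. On AG those for ubiquitin were higher by 0.65 to 0.74, for GAPDH by 0.37 to 0.82 and for actin by 0.45. On ATH1 the ranges were 0.24 to 0.40, 0.21 to 0.54 and 0.16 to 0.37. There they were higher at 1 h already, with medians of 0.27, 0.25 and 0.22, against 0.34, 0.38 and 0.26 at 3 h. On AG the medians at 1 h were -0.17, -0.08 and 0.18. Over the scalings the 3 h value of the 25S probe set lay between 1.21 and 1.25 on AG and between 0.83 and 0.86 on ATH1. The AG GAPDH value was 0.82 ± 0.18 at the 5' probe set and 0.37 ± 0.18 at the 3' one. No explanation was tested, whether RNA quality, labelling or biology.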

How the results depend on the processing

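The alternatives with the trimmed mean taken without control probe sets, with chloroplast-encoded probe sets left out and with crossed hybridization numbers were chosen after seeing the data. No list median, cross-platform correlation or called value of a named gene changed sign in the alternatives run for it. Among control spikes, lys and phe did under quantile normalization, such as lys at 1 h on ATH1 from 0.21 to -0.03 and lys at 3 h on AG from 0.24 to -0.07. These spikes are among the brightest signals: a phe probe set stood at 23385.0 in the control on ATH1, where the array maxima were 22334.5 and 24435.4. Quantile normalization gives equal ranks equal values on every array, so it brings differences at the top near 0 whatever their cause. Of 75 alternative counts of calls 63 stayed within 1.5 times the reported count, as did 52 of 54 counts of genes called on both platforms and 33 of 69 limma counts. Of 51 cross-platform correlations 32, of 80 list medians 56 and of 18 SDs between hybridizations 2 moved by less than their spread. The 128 called values of named genes kept their sign throughout; 128 were still called with quantile normalization, with no added amount, with no minimum signal and by size alone, 123 with scaling on shared genes, 105 with an added amount of 20%, 104 with a minimum of 50% and 122 without each hybridization in turn. No value of a list median depends on the rule for calls, so that alternative was not run for them.

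For calls in the order 1 h, 3 h and 3 h minus 1 h, an added amount of 20% gave 87, 237 and 136 on ATH1 and 93 and 53 in the last 2 contrasts on AG, since it shrinks differences of dim probe sets. No minimum signal gave 630, 608 and 794 on ATH1 and 76 at 1 h and 141 for 3 h minus 1 h on AG, with more probe sets counted. A minimum of 50% gave 98 at 1 h on ATH1. Leaving out each hybridization gave 154 to 276 calls at 1 h on ATH1, the highest without hybridization 2 of the 1 h RNA. Without chloroplast-encoded probe sets the ATH1 counts were 127 at 1 h and 363 at 3 h, and with the trimmed mean without control probe sets they were 153, 388 and 251 on ATH1 and 46, 155 and 85 on AG.

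The cross-platform r was 0.439, 0.673 and 0.433 with no minimum signal, 0.806, 0.884 and 0.761 with a minimum of 50%, and without each hybridization 0.667 to 0.747, 0.8 to 0.86 and 0.618 to 0.744. Genes called on both platforms numbered 18 at 3 h with an added amount of 20% and 25 for 3 h minus 1 h with no minimum. The cause was not tested beyond the signal. Among the dimmest of 3 equal groups of genes r at 1 h was 0.622, among the middle group 0.623 and among the brightest 0.894. The dimmest group thus did not stand apart from the middle one.

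Pairing hybridizations by their number as a block in limma gave 560, 2117 and 1108 probe sets on ATH1 and 248, 1045 and 533 on AG. The numbers paired the arrays weakly, since the differences between hybridizations 1 and 2 correlated across probe sets between RNAs by -0.04, 0.04 and 0.01 on ATH1 and -0.01, 0.06 and -0.11 on AG. Crossing the numbers of the 3 h RNA on AG gave 324, 1169 and 598. The block uses up 1 residual degree of freedom. With no minimum signal limma gave 147, 1054 and 461 on ATH1 and 91, 824 and 280 on AG, and with an intensity trend 2469 at 1 h and 2874 for 3 h minus 1 h on ATH1; for both the cause was not tested.

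Leaving out 1 hybridization in limma, which assumes that the lone hybridization of an RNA varies like the others, gave 59 to 1949 at 1 h, 621 to 3581 at 3 h and 207 to 2547 for 3 h minus 1 h on ATH1, and 67 to 539, 498 to 1170 and 229 to 619 on AG. At 1 h on ATH1 the count was 64 and 59 without hybridizations 1 and 2 of the control, 750 and 1949 without those of the 1 h RNA and 358 without either of the 3 h RNA. At 3 h on ATH1 it was 621 and 680 without those of the control and 844 and 871 without those of the 3 h RNA. For 3 h minus 1 h on ATH1 it was 692 without either of the control and 207 and 258 without those of the 3 h RNA. On AG it was 85 and 67 at 1 h without those of the control and 126 and 142 without those of the 1 h RNA, and 543 and 498 at 3 h without those of the control. For 3 h minus 1 h on AG it was 439 without either of the control, 229 and 248 without those of the 1 h RNA and 450 without hybridization 1 of the 3 h RNA. Fewer arrays leave fewer residual degrees of freedom.

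The Aux/IAA median on ATH1 was 1.18 at 1 h and 0.87 at 3 h with scaling on shared genes, 2.65 and 1.46 with no added amount, 1.42 and 0.71 with 20%, 0.56 and 0.28 with no minimum, 1.22 and 0.92 with a minimum of 50%, and 2.02 to 2.37 and 1.04 to 1.23 without each hybridization. With 3 members above the minimum, the loss or gain of a member at these minimum signals moved it. The GH3 median was 2.96 and 3.28 with no added amount, 2.74 and 3.05 with 20%, and 2.12 and 1.90 with no minimum. The expansin and XTH median was 0.78 and 0.90 with a minimum of 50%, and at 3 h 0.73 with no added amount and 0.60 with 20%. The root marker median at 1 h was 0.05 with quantile normalization and 0.08 to 0.22 without each hybridization.

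The SD between hybridizations for control, 1 h and 3 h was 0.305, 0.523 and 0.346 on ATH1 and 0.264, 0.284 and 0.341 on AG with no minimum, and 0.195, 0.332 and 0.216, and 0.206, 0.231 and 0.271, with no added amount. Quantile normalization gave 0.169, 0.306 and 0.187 on ATH1 and 0.251 for 3 h on AG. Dim signals limit what can be seen: for the 1 h RNA on ATH1 the dimmest of 3 equal groups of probe sets held 96 of those at least 2-fold apart between hybridizations, the middle group 9 and the brightest 0.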

Other observations

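The family scan and its genes, the comparison of spike signals, the nuclear photosynthesis transcripts and the share of lower calls without chloroplast-encoded probe sets are tests chosen after their results were seen; the others were set before. Among gene families on ATH1, 3 plant defensin genes were lower in the 3 h RNA than in the control: PDF1.2 (AT5G44420) at -1.67 ± 0.07, PDF1.4 (AT1G19610) at -1.44 ± 0.09 and PDF1.2b (AT2G26020) at -1.23 ± 0.09, the last on a probe set of the type that can detect related sequences. The defensin PDF2.5 (AT5G63660) stood at 0.07 ± 0.03. The PDF symbols also hold peptide deformylases, and the 6 members had a median of -0.71, which was -0.73 with scaling on shared genes. The sugar transporter genes SWEET16 (AT3G16690) and SWEET17 (AT4G15920) stood at -0.83 ± 0.04 and -0.81 ± 0.10 at 3 h. In the other direction, SWEET1 stood at 0.38 and SWEET10 at 0.21. The 6 SWEET genes had medians of -0.33 at 1 h and -0.47 at 3 h, with 0 called. Tau-class glutathione S-transferases went both ways at 3 h: GSTU25 stood at 3.39 and GSTU22 (AT1G78340) at 1.27, against -1.16 for GSTU18 and -1.01 for GSTU26 (AT1G17190), whose call was lost without hybridization 1 of the control or hybridization 2 of the 3 h RNA. Glucosyltransferase genes UGT73B5 (AT2G15480) and UGT76D1 (AT2G26480) were higher at 3 h by 1.70 ± 0.11 and 1.19 ± 0.14. Together with UGT73B4 they were the 3 of 27 UGT genes called at 3 h, where the family median was -0.02. PUB23 (AT2G35930), a ubiquitin ligase gene, stood at 0.98 ± 0.09 at 1 h and -0.01 at 3 h.

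The scan took 30 families with at least 5 members, and 10 of their 60 medians lay outside the 95% range of random lists, where 3.0 would by chance. The other medians outside were -0.34 for SCPL, -0.34 for BGLU, -0.37 for GSTU and -0.20 for TBL at 3 h, and -0.34 for CYP, 0.41 for PUB and 0.11 for UGT at 1 h. CYP mixes cyclophilins with cytochromes P450. These signs held under quantile normalization, scaling on shared genes and without each hybridization. Not all of the medians stayed outside the 95% ranges. Without each hybridization PUB lay between 0.09 and 0.57, where its range ended at 0.27. TBL lay between -0.16 and -0.06, where its range began at -0.17, and UGT between 0.03 and 0.14, where its range ended at 0.11. Under quantile normalization UGT stood at 0.07.

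Chloroplast-encoded transcripts were lower in both treated RNAs than in the control; an effect of brightness is excluded as the whole cause, since their median of -0.63 at 1 h lay below -0.03, the lower bound for other probe sets of the same signal. A separate labelling of the control may account for part of it. The labels name a first labelling on ATH1, and the control titles carry the mark (a) on both platforms. The dap and trp spikes were lower in the treated RNAs, dap with a median of -0.50 or below on both platforms, and so was the dim thr spike on ATH1. However, lys and phe were higher by 0.08 to 0.41. Under quantile normalization they were near 0 or of changed sign. That method sets the brightest signals of all arrays equal, and these spikes are among the brightest. The change under it therefore does not bear on labelling. Between the treated RNAs the median was -0.09, just outside the random range of -0.07 to 0.05, and members went both ways, with atpA at -1.85 at 1 h and -0.88 at 3 h, so a shift shared by both treated RNAs does not cover every member. Less green tissue also stays open. For 7 nuclear-encoded photosynthetic transcripts the median at 1 h was -0.20. It lay between the bounds of -0.32 and -0.16 set for and against that explanation, but below the random range of -0.11 to 0.24. Between the treated RNAs it was -0.33, below the random range of -0.24 to 0.15. LHCB4.1, LHCB4.2 and LHCB4.3 are related genes among the 7, so the members are not independent. At 3 h the nuclear-encoded median was -0.50, below the random range of -0.24 to 0.26, and the chloroplast median was -0.79. At both times 7 of 7 were below 0. With 1 control RNA, labelling and treatment cannot be told apart, and an effect of auxin on these transcripts remains untested.

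Lower probe sets made up 34.0% of the calls at 1 h on ATH1 (exact binomial 95% interval 26.5 to 42.2) and 13.3% on AG (5.1 to 26.8, from 45 calls). The intervals treat calls as independent, which they are not: 23 of the 51 lower calls on ATH1 were chloroplast-encoded. They cover no spread between plants, so they are too narrow as a measure of uncertainty. Without the dim hybridization 1 of the 1 h RNA the share was 39.0%, above that interval. That was the result set beforehand against that array as the cause. It cannot decide the question, because leaving out a hybridization also loosens the rule for calls. Without chloroplast-encoded probe sets the ATH1 share was 22.0%; their 23 calls were all lower, so leaving them out could not have raised it, and their part in the gap stays open. Among the 1485 genes on both platforms 2 of 14 calls on ATH1 and 1 of 10 on AG were lower. No biological explanation was tested.

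At 3 h 21 genes were called on 1 platform and not on the other. Their median difference on the other platform was 0.86 in the direction of the call, near the 2-fold threshold, and each of the 21 had the same sign there. A difference close to the threshold is a candidate explanation for these calls as a group; AT4G26010, at -0.93 on ATH1 and -2.52 on AG, has the widest gap between the platforms. No biological explanation was tested, and the platforms carry different probes for a gene.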
